A study of Caenorhabditis elegans with 2 samples.

How the data were processed

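The series holds chromatin immunoprecipitation followed by sequencing (ChIP-seq) of COG-1, an NK6-type homeodomain transcription factor, in Caenorhabditis elegans. Per the labels, the worms were of strain OP541, an unc-119 mutant background with the integrated transgene wgIs541, which stably expresses COG-1 with a GFP-FLAG tag at its C-terminus. Hermaphrodite mid-embryos were collected 3 h after synchronization by egg bleaching, chromatin was sonicated, and the tagged protein was precipitated with an antibody against GFP. Both samples belong to 1 group and are labelled biological replicates 1 and 2. No input or untagged library was among the samples analysed here.

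The deposited files were lists of regions for 2 genome builds, ce11 and ce10. The pooled relaxed lists are labelled as peaks and background for input to the thresholding step, so a region there need not be enriched. Per the deposited file listing, a relaxed list was made for each replicate and for the pooled replicates from the alignments together with a control alignment, and a thresholded list was derived from these with the irreproducible discovery rate (IDR), which rates how alike regions rank in both replicates. The aligner, the peak caller, their versions and the IDR threshold were not given in the sources used here. The authors' caller gave each region a signal value, whose scaling to sequencing depth was not given, so it was used only to describe and rank regions within a list. The deposited lists also hold a q-value per region on the −log10 scale, capped at a shared highest value (3.45 in the pooled ce11 list). Every peak of the IDR list was a region of the pooled list with the same values, and the 1841 IDR peaks were the 1841 pooled regions of highest signal. The IDR list is labelled optimal, and a cut of the pooled list by signal alone would give the same peaks. Being in it therefore does not show that a given peak ranked alike in both replicates. Read depth per sample was not used here, so precision rests on numbers of peaks, and all intervals cover counting error only.

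Coordinates are those of ce11 and are counted from 1. The reference was the WBcel235 assembly, which is the same sequence as ce11, with the Ensembl release 115 annotation of protein-coding and non-coding genes, and 0 regions of the 4 ce11 lists ran past a chromosome end. No coordinates were moved between builds. The ce10 lists were compared by counts and chromosome shares only, with ce11 chromosome lengths as the expectation. Mitochondrial DNA was left out.

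Groups, alternatives, tests, gene lists and motifs were fixed before the data were examined. A gene was taken to hold a peak when a summit lay from 1000 bp upstream to 500 bp downstream of its annotated start. Summits were placed, in this order, in gene-start windows of protein-coding genes, coding exons, other exons (untranslated and non-coding), introns and intergenic sequence. The observed shares were set against 10000 random placements within chromosomes with a two-sided empirical p whose smallest possible value is 0.0001. Chromosomes were tested with a two-sided exact binomial test against their share of nuclear genome length. The 18 gene lists were tested with two-sided Fisher's exact tests against all other protein-coding genes. They covered the pathway of the ASE taste neurons, vulva and uterus, panneuronal genes, muscle, pharynx, intestine, epidermis, maternal germline genes, cell cycle, homeobox, nuclear receptor and bHLH genes, ribosomal proteins, proteasome, heat shock and chaperone genes, collagens and cuticle, histones and chemoreceptors. There were 5 symbols that matched no protein-coding gene of the annotation: lsy-6, which is a microRNA gene and was looked up by its position, opt-2, elt-5, daf-21 and ram-4. Genes for tRNA, snoRNA and snRNA counted as near a peak within 500 bp of a summit and were set against the same random placements. The 9 short sequences were searched on both strands within 50 bp of each summit and in 1 window of the same size centred 400 bp to one side, and the paired shares were compared with exact McNemar tests. Benjamini-Hochberg adjustment was made within each family, over 5 locations, 6 chromosomes, 18 lists, 3 RNA classes or 9 sequences. Overlap of the top regions of both replicates was set against 1000 random placements, whose smallest possible p is 0.000999. The tagged locus was compared with windows of 40 kb to either side of points spaced 10 kb apart along the chromosomes. Peaks and genes are not replicates, so these p-values concern placement and counting, not variation between animals.

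The genes named are those at the 20 peaks of highest signal, by the gene-start window or otherwise the nearest gene start, up to 4 members per list with the strongest peak, and cog-1, lsy-6, die-1, lim-6, fozi-1, che-1, unc-37, egl-17 and unc-119 whether or not they held a peak. Other genes named were chosen after their values were seen. Alternatives covered the other build, the stronger part of the IDR list, the pooled list, other windows, distances and flanks, reciprocal overlap of 50%, gene numbers as expectation, nearest gene only, a background of genes with a pooled region, 10000 random lists matched on upstream length in 10 bins, and each replicate's own list with the other replicate left out. For the last, the 1841 regions of highest signal in the remaining replicate's relaxed list were used, without an IDR threshold. Leaving out peaks near tRNA genes, placing summits in coding exons before gene-start windows and comparing summits with gene-start windows of matched GC content (within 2 bases) were chosen after the data were examined.

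The calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. They were tested on simulated data with the real number of peaks and the 19973 protein-coding genes. In 50 rounds of random summits, 4 of 900 gene list tests and 6 of 250 location tests passed an adjusted p of 0.05. With peaks planted at 48.5% of the proteasome genes, the list passed in 50 of 50 rounds. That share was above the 21.2% observed for this list, so the rounds do not give the power at the observed shares. Random summits were spread evenly along chromosomes, unlike the real ones. A TTAATT planted in 200 summit windows raised the measured difference by 9.02 percentage points, against 9.02 points planted in windows that had lacked it. Both values follow from the same windows, so their equality checks only that matches are counted.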

Results

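COG-1 is a homeodomain transcription factor of the NK6 family, known for its part in the left-right fate choice of the ASE taste neurons and in the vulva and uterus. The data ask where the tagged protein was found along the genome of C. elegans mid-embryos. They comprise lists of regions from 2 biological replicates of 1 group, COG-1-GFP mid-embryos collected 3 h after synchronization. The IDR list in ce11 held 1841 peaks with a median width of 450 bp, a median authors' signal of 111 and a range from 77.7 to 769. The relaxed lists were longer, with 21617 regions for replicate 1, 20247 for replicate 2 and 22583 for the pooled reads. Among them 2033, 3522 and 2976 regions had a q-value under 0.05. The ce10 list held 1834 IDR peaks.

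The strongest peak lay on chromosome III at 8043777 to 8044161, 529 bp upstream of the start of K12H4.5, with a signal of 769. It was followed by peaks 273 bp upstream of rpl-3, which encodes a large-subunit ribosomal protein (III, 3867423 to 3867731, signal 563), 522 bp upstream of ftt-2, a 14-3-3 protein gene (X, 11605656 to 11606428, signal 529), and 97 bp upstream of tos-1 (V, 9344098 to 9344471, signal 504). K12H4.5 and rpl-3 ranked 1 and 2 in each replicate's own list, and ftt-2 and tos-1 ranked 4 and 5 in replicate 1 and 3 and 4 in replicate 2. The region at ftt-2 had a second summit that ranked 16 (signal 372), and the 2 summits lay inside the non-coding RNA genes F52D10.7 and F52D10.9. Of the 20 strongest peaks, 12 lay in the window of a protein-coding gene start. Besides those named, they lay at K01G5.10 with tasp-1, at cdc-48.1, which encodes a AAA ATPase, at rpl-15 with K11H12.8, at his-67 and his-68 with alg-5, at rpl-20 with Y17G9B.5, at rpl-35 and at H41C03.3, with signals from 372 to 484.

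The other 8 of the 20 strongest peaks lay outside these windows and were assigned to the nearest gene start. These were W03C9.1 at 1331 bp, F55C5.17 at 1104 bp, Y43F8C.7 at 830 bp, Y37A1B.7 at 9774 bp, F13D11.3 at 6305 bp, hrg-5 at 3279 bp, F20B6.9 at 1816 bp and cest-16 at 3407 bp. Annotated non-coding RNA genes lay within 500 bp of 6 of the 8 summits. How often such genes lie that near to other peaks or to random positions was not computed. The summits assigned to W03C9.1, F55C5.17 and Y43F8C.7 were near a snoRNA gene, W03C9.9, C51F7.4 and Y43F8C.22 respectively. The summit assigned to Y37A1B.7 (IV, 14034006) was 2 bp from the microRNA gene mir-52, and the summit assigned to hrg-5 (IV, 11026149) was 37 bp from mir-51. The summit assigned to F13D11.3 lay in the non-coding RNA gene F13D11.7. Of the peaks inside windows, the summit at H41C03.3 (II, 5844842) was 23 bp from sls-2.1, a gene of the spliced leader SL2 RNA. None of the 20 summits lay within 500 bp of a tRNA gene.

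Nearly all IDR peaks were found in each replicate alone, and the order of their strength was partly shared. Summits of 1833 of the 1841 peaks (99.6%) lay in a region of both replicates' relaxed lists. The signal of the replicates over these peaks had a Spearman rho of 0.60, and over the 8764 pooled regions present in both (38.8% of 22583) it was 0.64. These correlations run across regions, which are not independent replicates. Of the 1841 strongest regions of replicate 1, 68.7% had their summit in one of the 1841 strongest regions of replicate 2, against 0.827% ± 0.213 (SD over 1000 random placements, permutation p = 0.000999, the smallest they can give). The IDR list consisted of the 1841 regions of highest signal in the pooled reads, to which both replicates contributed, so the first share is not independent evidence of repeatability.

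Peaks were concentrated at the starts of protein-coding genes and were rare in coding sequence. There were 1036 summits (56.3%, exact 95% interval 53.97 to 58.6) in gene-start windows, against 25.7% ± 1.01 (SD) of random placements, 2.19 times as many. Coding exons outside these windows held 4 summits (0.217%, interval 0.0592 to 0.555) against 17.9% ± 0.892 at random. With coding exons inside the windows counted as well, it was 17 summits (0.923%, interval 0.539 to 1.47) against 24.3% ± 1.00. Other exons, which include untranslated regions and non-coding RNA genes, held 189 summits (10.3%), 1.86 times the random share. Introns with 279 summits (15.2%) and intergenic sequence with 333 (18.1%) were below the random shares, at 0.542 and 0.790 times. All 5 differences reached an adjusted permutation p of 0.0001, the smallest that the placements can give. The median distance to the nearest gene start was 592 bp. It was under 200 bp for 460 peaks (24.99%) and over 5000 bp for 159 (8.64%), and 1330 summits (72.2%) lay upstream of the start. Within 500 bp upstream to 250 bp downstream of a gene start the excess was 3.39 times. The coding exon ratio, based on 4 peaks, was 0.0242 without replicate 1 and 0.0364 without replicate 2, against 0.0121 with both.

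**Figure D1:**
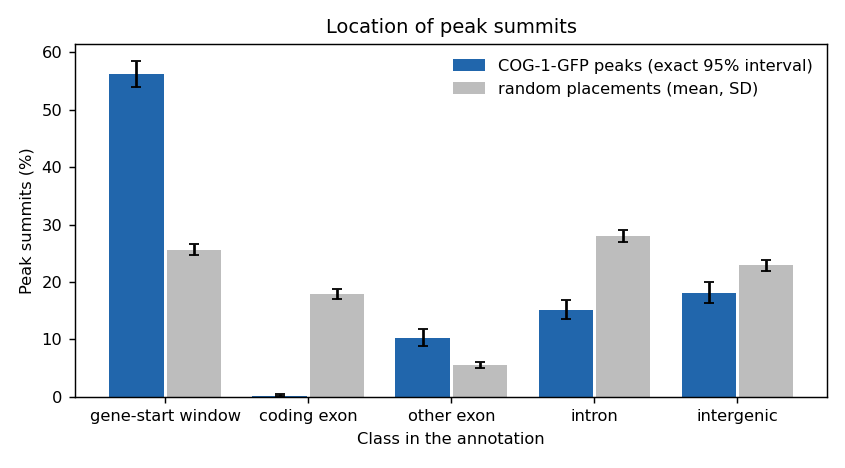
Share of peak summits (%) in each annotation class for the 1841 IDR peaks (blue, exact 95% intervals) and for 10000 random placements within chromosomes (grey, mean and SD). Gene-start windows held 56.3% of summits against 25.7% at random, and coding exons outside them 0.217% against 17.9%.

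The X chromosome and chromosome I held more peaks than their length would give, and chromosome V held fewer. The X chromosome had 427 peaks (23.2%, exact 95% interval 21.3 to 25.19, or 24.1 per Mb), 1.31 times its share of genome length (exact binomial test, adjusted p = 5.86e-09). Chromosome I had 342 peaks, 1.24 times its share (exact adjusted p = 6.78e-05), and chromosome III had 286, 1.13 times (adjusted p = 0.0333). Chromosome V, which carries much of the chemoreceptor gene families, had 233 peaks, or 11.1 per Mb (0.607 times, exact adjusted p = 2.99e-19). Chromosome IV had 268 peaks (0.834 times, exact adjusted p = 0.00136) and chromosome II 285 (1.02 times, adjusted p = 0.770). On the X chromosome 210 of 427 peaks (49.2%) lay in gene-start windows, against 826 of 1414 (58.4%) on the autosomes (Fisher's exact p = 0.000832). Random placements gave 21.9% and 26.8%, so the excess was 2.25 times on the X chromosome and 2.18 times on the autosomes. The median distance to a gene start was 928 bp on the X chromosome against 489.5 bp. The X chromosome carried 154 protein-coding genes per Mb and the autosomes 209. Peaks near tRNA genes made up 17.3% of peaks on the X chromosome (74 of 427) and 4.81% on the autosomes (68 of 1414), and 276 of the 612 tRNA genes (45.1%) were on the X chromosome. Without peaks near tRNA genes the X chromosome held 1.18 times its share (exact adjusted p = 0.00209). With gene numbers in place of length as the expectation, the X chromosome held 1.70 times its share (exact adjusted p = 1.18e-27), and chromosome II was below it (0.896 times, adjusted p = 0.0419). The value of chromosome III did not pass in the 921 peaks of higher signal (1.12 times, exact adjusted p = 0.181).

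**Figure D2:**
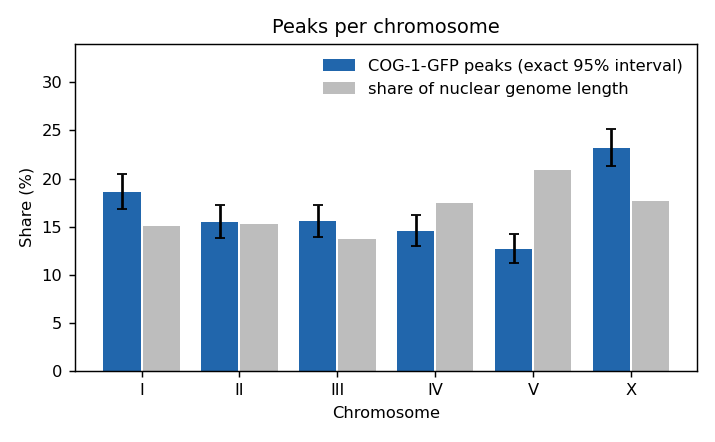
Share of the 1841 IDR peaks on each chromosome (%, blue, exact 95% intervals) beside the chromosome's share of nuclear genome length (%, grey). The X chromosome held 23.2% of peaks on 17.7% of the length, and chromosome V 12.7% on 20.9%.

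Genes for ribosomal proteins held peaks far more often than other genes. A peak lay at 52 of 81 ribosomal protein genes (64.2%, exact 95% interval 52.8 to 74.6) against 6.59% of all other protein-coding genes, an odds ratio of 25.4 (95% interval 15.8 to 41.7, Fisher's exact adjusted p = 1.90e-39). The strongest were at rpl-3 (signal 563), rpl-15 (IV, 394), rpl-20 (IV, 385) and rpl-35 (III, 373), with summits 273, 344, 290 and 445 bp upstream. These 52 genes shared 50 distinct peaks, whose median rank was 652. The odds ratio was 7.88 with each peak given to its nearest gene start alone and 11 against genes that held a pooled region (exact adjusted p = 3.28e-21), and both passed. In all, 1362 of 19973 protein-coding genes (6.82%) held a peak, 356 peaks lay in the windows of more than 1 gene and 56 genes held more than 1 peak.

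Genes for chaperones, proteasome subunits and histones also held peaks more often than other genes. In the heat shock list 15 of 52 genes held a peak (odds ratio 5.59, interval 2.84 to 10.5, Fisher's exact adjusted p = 7.22e-06). They included hsp-1, which encodes a constitutive Hsp70 (rank 69, signal 275), dnj-29, a J-domain protein gene (rank 86, signal 261), hsp-110 (rank 175, signal 211) and hsp-60, the mitochondrial chaperonin gene (rank 178, signal 210), and 10 of the 15 were dnj genes. In the proteasome list it was 7 of 33 genes (odds ratio 3.69, interval 1.351 to 8.75, exact adjusted p = 0.0216), led by rpn-3 (rank 175), rpn-9 (rank 356), rpt-2 (rank 714) and rpn-7 (rank 889). The peak at rpn-3 was also the peak at hsp-110, whose start lies on the other side of it. Of 72 histone genes, 14 held a peak (odds ratio 3.32, interval 1.71 to 6.05, exact adjusted p = 0.00141), among them his-67 and his-68 (rank 13) and his-61 and his-62 (rank 51). These were 8 distinct peaks, most between divergent gene pairs, and histone genes occur in near-identical copies that can share reads, so their peaks are uncertain. With each peak given to its nearest gene start alone, the heat shock (odds ratio 2.36), proteasome (3.04) and histone (1.41) lists did not pass, with adjusted p of 0.0912, 0.0554 and 0.574, and the ribosomal protein list did. Against genes that held a pooled region, heat shock (odds ratio 2.82, exact adjusted p = 0.0129) and histone genes (6.73, adjusted p = 6.16e-05) passed and proteasome genes (1.88) did not. Without replicate 1 the proteasome list (odds ratio 3.08, exact adjusted p = 0.0554) and without replicate 2 the histone list (2.33, exact adjusted p = 0.0760) did not pass. In the permutation test matched on upstream length, heat shock (3.57 times) and ribosomal protein genes (6.30 times) passed, whereas the proteasome list (2.33 times, adjusted p = 0.0837) and the histone list (1.63 times, adjusted p = 0.166) did not.

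Chemoreceptor genes and collagen genes held peaks less often than other genes. Only 7 of 1281 chemoreceptor genes (0.546%) held a peak (odds ratio 0.0703, interval 0.0282 to 0.146, Fisher's exact adjusted p = 7.50e-30, or 0.137 and adjusted p = 1.98e-11 against genes that held a pooled region), of which the strongest were at sre-23 (rank 26), sri-5 (rank 184), srh-16 (rank 388) and sre-1 (rank 448). Of 175 collagen and cuticle genes, 4 held a peak, col-85, col-185, col-38 and col-71 (odds ratio 0.318, interval 0.0854 to 0.830, exact adjusted p = 0.0438), and the peak at col-38 (rank 655) was also assigned to rpl-5. The collagen result did not pass without replicate 2 (odds ratio 0.422, exact adjusted p = 0.102), nor with genes holding a pooled region as background (0.552, adjusted p = 0.769). It also did not pass when matched on upstream length (0.349 times, permutation adjusted p = 0.0837) or in the 921 stronger peaks (odds ratio 0.640, exact adjusted p = 0.819). The peaks at col-85 and col-185 lay within 500 bp of a tRNA gene, and without such peaks the list passed with an odds ratio of 0.162 (exact adjusted p = 0.00390).

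Lists of tissue genes and of transcription factor families did not differ from other genes at an adjusted p of 0.05. Among muscle genes 5 of 25 held a peak (odds ratio 3.42, interval 1.00 to 9.42, Fisher's exact adjusted p = 0.0636), with unc-112, the kindlin gene (rank 138, signal 227), mup-2 (rank 711), tnt-2 (rank 1579) and unc-98 (rank 1698) strongest. This list passed without replicate 2 (odds ratio 5.63, exact adjusted p = 0.00366) and when matched on upstream length (3.86 times, permutation adjusted p = 0.0369), but not without replicate 1 (odds ratio 1.88, exact adjusted p = 0.473) or against genes that held a pooled region (1.43, adjusted p = 0.912). Among cell cycle genes 4 of 29 held a peak (odds ratio 2.19, exact adjusted p = 0.264), lin-35, the retinoblastoma homologue (rank 31, signal 334), cye-1 (rank 538), cdk-4 (rank 665) and pcn-1 (rank 884), and without replicate 1 the list passed (odds ratio 3.61, adjusted p = 0.0419). It did not pass without replicate 2 (odds ratio 3.01, exact adjusted p = 0.0948) or against genes that held a pooled region (0.858, adjusted p = 1). Panneuronal genes had 2 of 23 with a peak, syd-2 and maco-1 (exact adjusted p = 0.802), and maternal germline genes 1 of 25, mex-1 (adjusted p = 1). No peak lay at the 14 pharynx, 20 intestine or 21 epidermis genes (Fisher's exact adjusted p from 0.648 to 0.802). That allows shares of up to 23.2%, 16.8% and 16.1% (upper exact 95% limits). With each peak given to its nearest gene start alone, the odds ratio was 2.65 for epidermis (exact adjusted p = 0.195), 0.592 for intestine and 0 for pharynx. Homeobox genes had 6 of 97 (odds ratio 0.901, exact adjusted p = 1), led by irx-1 (rank 159), ceh-38 (rank 168), ceh-20 (rank 283) and nob-1 (rank 933). Nuclear receptor genes had 12 of 274 (odds ratio 0.623, exact adjusted p = 0.262), led by nhr-1, nhr-255, nhr-48 and nhr-59. Among bHLH genes 1 of 40 held a peak, aha-1 (exact adjusted p = 0.783). Without replicate 1 the odds ratios of maternal germline and bHLH genes were 1.20 and 0.726, against 0.569 and 0.350 with both replicates. Without replicate 2 they were 0.600 and 0.758.

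**Figure D3:**
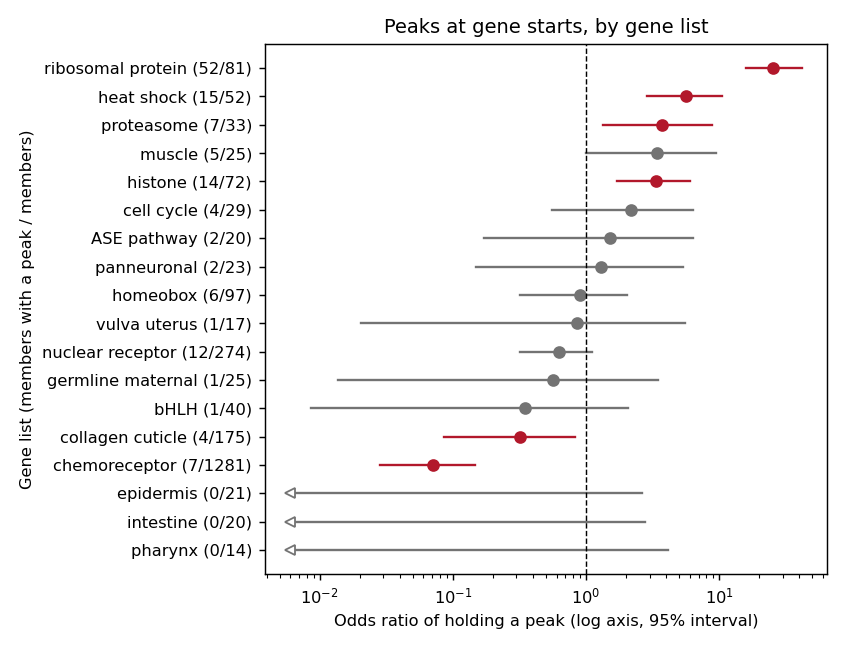
Odds ratio of holding a peak for the members of each of 18 gene lists against all other protein-coding genes (log axis, points with 95% intervals, red for an adjusted p under 0.05, open triangles for lists with no peak). Ribosomal protein genes lie furthest above 1 at 25.4 and chemoreceptor genes lie at 0.0703.

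Genes known to act with cog-1 in the ASE neurons or in the vulva did not differ detectably from other genes in holding peaks. The chromatin came from mid-embryos and not from ASE or vulval cells alone. A missing peak therefore does not show that COG-1 is absent from a gene in those cells. In the ASE pathway list 2 of 20 genes held a peak (odds ratio 1.52, interval 0.171 to 6.36, Fisher's exact adjusted p = 0.802). They were unc-37, which encodes the Groucho co-repressor (I, summit at 6745599, 270 bp upstream, rank 460, signal 150), and cog-1 itself (II, summit at 14901933, 560 bp upstream, rank 1394, signal 89.8). The cog-1 peak lies at the locus of the tagged protein, which the transgene may carry in extra copies. The homeobox list also counts cog-1 among its genes with a peak. In the vulva and uterus list 1 of 17 genes held one (odds ratio 0.854, exact adjusted p = 1), egl-17, an FGF gene expressed in vulval cells (X, summit at 489937, 252 bp inside the gene, rank 201, signal 203). That summit lay inside an annotated tRNA gene. Without peaks near tRNA genes no peak remained in this list (odds ratio 0, exact adjusted p = 0.795). With each peak given to its nearest gene start alone, its odds ratio was 2.42 (exact adjusted p = 0.282). No IDR peak lay in the window of die-1, lim-6, fozi-1 or che-1, transcription factor genes of the ASE pathway, of the microRNA gene lsy-6, or of unc-119. The nearest IDR summit to the die-1 start was 2291 bp inside the gene (II, 10065626, rank 1096), that to lim-6 was 9584 bp away and that to che-1 11194 bp, and those to lsy-6, fozi-1 and unc-119 were over 30 kb away. In the pooled relaxed list, which also holds background, a region lay 22 bp from the lsy-6 start (V, 10647254) at rank 11698 of 22583. Neither replicate's own list had a region in that window. The window of die-1 held a region in the pooled list (rank 8599) and in the lists of replicate 1 (rank 6682) and replicate 2 (rank 13906). The window of lim-6 held one in the pooled list alone (rank 20914), that of fozi-1 in replicate 2 alone (rank 14873), and that of che-1 in none.

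Genes of tRNAs, snoRNAs and snRNAs held peaks many times more often than random placement gave. A summit lay within 500 bp of 156 of 612 tRNA genes (25.5%, exact 95% interval 22.1 to 29.1) against 2.18% ± 0.676 (SD) at random, 11.7 times as many. For snoRNA genes it was 79 of 346 (22.8%, interval 18.5 to 27.6) against 2.09%, 10.9 times, and for snRNA genes 12 of 129 (9.30%, interval 4.90 to 15.7) against 1.80%, 5.16 times. Each had an adjusted permutation p of 0.0001, the smallest that the placements can give. There were 142 IDR peaks (7.71%) near a tRNA gene. Within 200 bp the ratios were 24.1, 19.2 and 10.1 times. Genes of these classes occur in near-identical copies and clusters, so single genes were not ranked.

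The 3 homeodomain cores were less frequent at summits than in the flanks, and a GA repeat was more frequent. GAGAGA lay within 50 bp of 28.9% of summits (532 of 1841, exact 95% interval 26.8 to 31.0) against 5.54% of flanks 400 bp away, 23.4 points more (interval 21.02 to 25.7, exact McNemar adjusted p = 5.75e-78). At the 50 peaks of ribosomal protein genes it was at 12% of summits against 4% of flanks, which did not pass (exact McNemar adjusted p = 0.656). TTAAT, which holds the TAAT bound by many homeodomains, was at 13.0% of summits against 29.2% of flanks (-16.2 points, exact adjusted p = 2.12e-33), and the longer NK6-like TTAATT at 6.14% against 16.5% (-10.3 points, adjusted p = 1.01e-23, or -6.68 points without replicate 2). The palindrome TAATTA was at 2.66% against 5.27% (-2.61 points, exact adjusted p = 8.77e-05), and its difference did not pass without replicate 2 (-0.81 points, exact adjusted p = 0.251) or with a flank 1000 bp away (-1.20 points, adjusted p = 0.0507). The permuted core TATTAT, which served as a composition control, was also lower, at 4.29% against 10.1% (exact adjusted p = 1.33e-11). So were the T run TTTTTT (17.5% against 41.9%, exact adjusted p = 8.32e-58) and the GATA-type site TGATAA (2.55% against 8.80%, adjusted p = 3.19e-16). The E-box CANNTG was higher at summits (39.2% against 30.04%, 9.13 points, exact adjusted p = 7.75e-09, or 4.89 points within 100 bp, adjusted p = 0.00300), and the difference of CCAAT did not pass (16.2% against 17.9%, adjusted p = 0.170). It passed within 100 bp (-4.51 points, exact adjusted p = 0.00300) and with a flank 1000 bp away (-4.73 points, adjusted p = 0.000225). Summit windows had 47.6% GC and flanks 35.5%. Against gene-start windows of matched GC content, GAGAGA was still higher at summits (28.9% against 8.80%, exact McNemar adjusted p = 1.28e-53), whereas TTAAT differed by 1.41 points (interval -0.618 to 3.44, adjusted p = 0.285), TTAATT by 0.109 points (interval -1.37 to 1.58, adjusted p = 0.942), TAATTA, now higher, by 0.923 points (interval 0.0148 to 1.83, adjusted p = 0.109) and the E-box by 0.272 points (adjusted p = 0.942). The T run was then higher at summits (2.99 points, exact adjusted p = 0.0250), CCAAT lower (-4.78 points, adjusted p = 0.00112) and TGATAA still lower (-1.85 points, adjusted p = 0.00799). The matched windows came from starts of genes without a peak and were not kept clear of coding exons, where few summits lay. They therefore match GC content but not the kind of sequence.

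**Figure D4:**
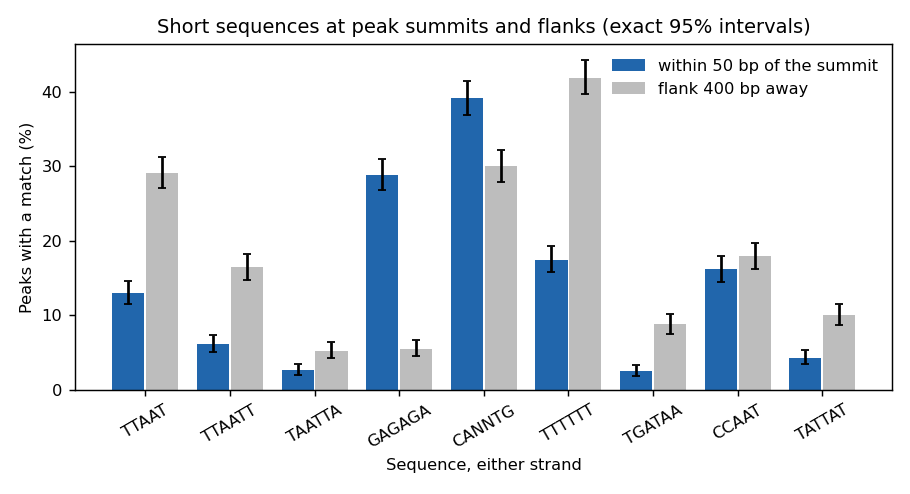
Share of the 1841 IDR peaks (%) with each short sequence on either strand within 50 bp of the summit (blue) and in a flank of the same size 400 bp away (grey), with exact 95% intervals. GAGAGA stands at 28.9% against 5.54%, and the cores TTAAT and TTAATT are lower at summits.

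The cog-1 gene itself (II, 14902493 to 14907533, plus strand), the locus of the tagged protein, lay in a dense group of regions, nearly all outside the IDR list. Within 40 kb of its start there were 28 regions in replicate 1 and 33 in replicate 2, at percentiles 96.0 and 99.1 of 9982 windows of that size, whose medians were 17 and 16 regions. The pooled list had 34 regions there against a median of 18. Within 20 kb it had 26 against 9, at percentile 99.9. Only 1 of these regions was an IDR peak, the one 560 bp upstream of cog-1. The median signal of the regions within 40 kb was at percentile 92.8 in replicate 1 and 44.4 in replicate 2, and at 74.7 in the pooled list (34.4 against a median of 31.8). Within 20 kb it was at percentile 94.6 in replicate 1, 64.3 in replicate 2 and 91.5 in the pooled list (41.3 against a median of 31.7). The gene unc-119, whose mutation marks the strain, had its nearest pooled region 906 bp inside the gene at rank 13852.

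**Figure D5:**
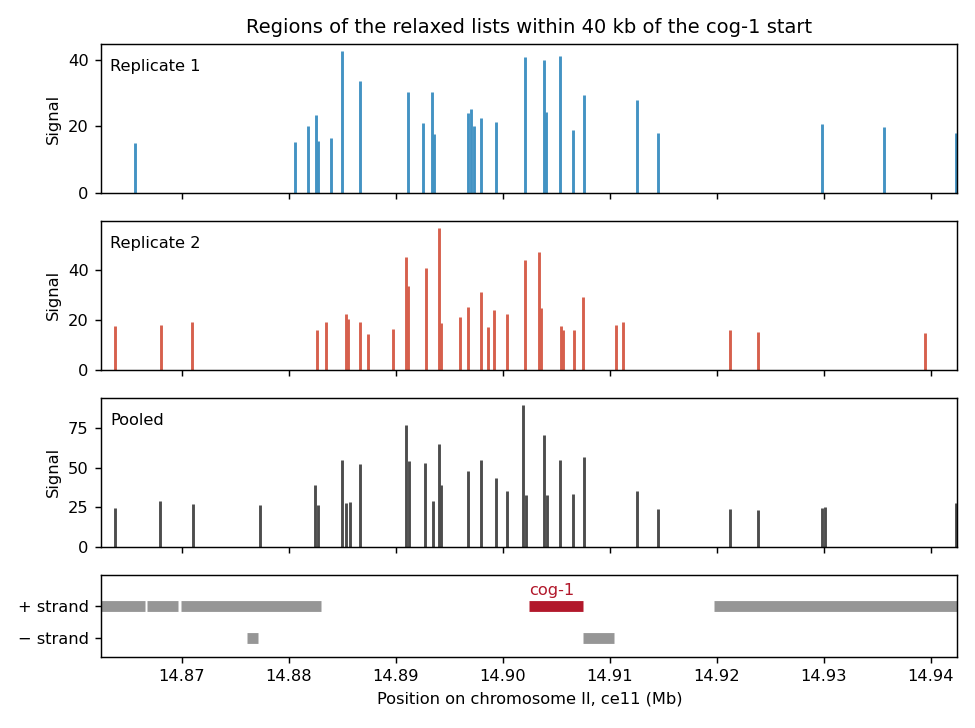
Summits of relaxed-list regions within 40 kb of the cog-1 start on chromosome II (ce11, Mb), each line as high as the authors' signal, for replicate 1, replicate 2 and the pooled list, with protein-coding genes below (cog-1 in red). Regions crowd upstream of and within cog-1, with 28, 33 and 34 regions in the 3 lists.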

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

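The choice of matched GC windows, the removal of peaks near tRNA genes and the placing of coding exons before gene-start windows were made after the data were examined; all other alternatives were planned. Of 343 recomputed values, 303 kept their side of the threshold (and their direction where they passed it) or their size, including all 40 without peaks near tRNA genes, all 5 locations and 3 RNA classes under each alternative, and the X, I, IV and V chromosomes. Values that passed in neither setting count as kept even where they changed direction. Cell cycle genes are an example, with an odds ratio of 2.19 in the main test and 0.858 against genes with a pooled region. Placing peaks by their midpoint gave the same gene-start and coding exon ratios as their summits (2.19 and 0.0121), so it tested little. The number of kept values is therefore not a measure of robustness. Unless stated, the cause of a change was not tested. With only 2 replicates, and no control library among the samples analysed here, leaving one replicate out can show little.

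The stronger part of the IDR list held 921 peaks by construction and the pooled list 22583. Reciprocal overlap of 50% lowered the share of peaks found in both replicates to 94.2% and the overlap of top regions to 65.6%, and the latter was 71.7% with the number of regions halved and 62.2% with it doubled. Chromosome II turned to 0.896 times with gene numbers as expectation, and chromosome III gave 1.12 times in the stronger peaks, where fewer peaks were tested.

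For gene lists, the nearest start alone left 1 enriched list in place of 4, with odds ratios of 3.04 (proteasome), 2.36 (heat shock) and 1.41 (histone). A background of genes with a pooled region gave 1.88 (proteasome) and 0.552 (collagen). Matching on upstream length gave ratios of 2.33 (proteasome), 1.63 (histone) and 0.349 (collagen), and the stronger peaks gave 3.802 (proteasome) and 0.640 (collagen). None of these values passed. Each of the last 3 settings left 1 depleted list in place of 2. With a replicate left out, odds ratios ran from 3.08 to 3.90 (proteasome), 2.33 to 3.36 (histone), 0.321 to 0.422 (collagen), 1.88 to 5.63 (muscle) and 3.01 to 3.61 (cell cycle), and depleted lists from 1 to 2. The lower proteasome value came without replicate 1, and the lower histone and higher collagen and muscle values without replicate 2.

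For short sequences, CCAAT passed with -4.51 points within 100 bp and -4.73 with a flank 1000 bp away, where the palindrome TAATTA gave -1.20 and did not pass. The E-box passed with 4.89 points within 100 bp against 9.13 within 50 bp. Leaving out a replicate gave -2.82 to -0.815 points for the palindrome. Against windows of matched GC content the differences were 1.41 (TTAAT), 0.109 (TTAATT), 0.923 (TAATTA), 0.272 (E-box), 2.99 (T run), -4.78 (CCAAT) and 0.815 points (TATTAT), and GAGAGA passed in the same direction as against flanks.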

Other observations

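The tests of gene classes, of microRNA, piRNA and lincRNA genes, of peaks by rank, of ribosomal peaks against windows of matched GC content and of the stretch around cog-1 were chosen after the data were examined; the others were set before their own results were seen. Over all 175 gene classes of at least 10 members that share a name stem, 11 held peaks more often than other genes and 6 less often (Fisher's exact tests, adjusted over the 175 classes). Beyond ribosomal proteins, histones and dnj chaperones, the classes with more peaks included mrpl genes of the mitochondrial ribosome (10 of 41, odds ratio 4.43, exact adjusted p = 0.00533), sec genes of protein secretion (7 of 19, odds ratio 8.01, adjusted p = 0.00410), mdt genes of the Mediator complex (7 of 20, odds ratio 7.39, adjusted p = 0.00462), vps genes of vesicle sorting (8 of 31, odds ratio 4.77, adjusted p = 0.0118) and dhhc genes (5 of 14, odds ratio 7.61, adjusted p = 0.0179). The lin class, named for cell lineage mutants, had 16 of 47 genes with a peak (odds ratio 7.12, exact adjusted p = 2.33e-06), led by lin-35 (rank 31), lin-54 (rank 38) and lin-59 (rank 96). The peak at lin-54 was also the peak at rpl-12, and that at lin-35 was also assigned to vps-51. Other peaks were shared as well, by sec-61.A with rps-18 (rank 396), mrpl-49 with rpl-28 (rank 736) and mrpl-37 with lin-38 (rank 1235). The unc class had 15 of 94 (odds ratio 2.61, exact adjusted p = 0.0179), and unc-50 and unc-69 shared the peak at rank 1086. The classes were tested with the gene-start window alone. Nearest gene starts and matching on upstream length, where the proteasome and histone lists did not pass, were not tried for them. Classes with fewer peaks were the chemoreceptor classes str (1 of 193 genes), srh (3 of 220), srw (0 of 109) and srx (none), the C-type lectins clec (3 of 240, exact adjusted p = 0.00243) and the F-box genes fbxa (2 of 170, adjusted p = 0.0135).

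A summit lay within 500 bp of 22 of 261 microRNA genes (8.43%, exact 95% interval 5.36 to 12.5) against 2.12% at random, 3.98 times as many (adjusted permutation p = 0.0003). Among them were mir-51, mir-52, mir-53, mir-54, mir-55 and mir-56, all 6 genes of that numbered series, at ranks 18, 9, 445, 235, 235 and 1735, where mir-54 and mir-55 shared a peak on the X chromosome. The microRNA genes mir-58a, mir-80 and mir-90 also held peaks, at ranks 1338, 1634 and 257. Of 15363 piRNA genes, 133 had a summit that near (0.866%) against 1.56% at random (0.553 times, permutation adjusted p = 0.00105), and of 194 lincRNA genes 17 did (8.76%, 2.15 times, adjusted p = 0.003). These genes are clustered, and 18 distinct peaks account for the 22 microRNA genes. The random placements were spread evenly along chromosomes, unlike the summits. Those lay 2.19 times as often as random in gene-start windows, 1.86 times in other exons and 0.542 times in introns. The piRNA and lincRNA ratios are of similar size, so they need not be particular to these genes. Placement by kind of sequence was not adjusted for.

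Further down the pooled list, regions lost the features of the IDR peaks taken as a whole. GAGAGA was at 29.4% of summits in the upper part of the IDR list, 28.4% in its lower part, 21.02% in the 1841 regions that followed it (ranks 1842 to 3682) and 8.93% in all 20742 lower regions. Coding exons outside gene-start windows held 0.326%, 0.109%, 1.14% and 6.10% of these summits, against 17.9% of random placements for the whole IDR list, and GC content at summits was 48.9%, 46.2%, 42.4% and 35.7%. TTAATT was at 5.32%, 6.96%, 12.8% and 18.01% of summits, and only in the last set was it above the flanks (17.2%, exact McNemar p = 0.0252, not adjusted), where the permuted core TATTAT stood at 10.5% against 10.0%. In the whole pooled list 2976 of 22583 regions had a q-value under 0.05, so most of these lower regions did not.

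The strong peaks at ribosomal protein genes may reflect a ChIP signal common to highly transcribed genes of any polymerase. As that explanation needs, tRNA genes held summits 11.7 times as often as random placement gave, but a true signal of the tagged protein at open chromatin would give the same excess and transcription was not measured here, so the value favours neither. A TTAAT core under each of these summits was argued against, since 42 of the 50 had none within 50 bp. Whether the core is favoured at some of them stays open: 16% of summits held it against 8.72% in gene-start windows of the same GC content (7.28 points, 95% bootstrap interval -1.70 to 17.7), and the -26 points against flanks decide nothing, because summits had 49.0% GC and flanks 39.3%. That true signal and binding of COG-1 through other proteins also stay open, since no untagged or input library was analysed here.

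The lower frequency of homeodomain cores at summits is consistent with base composition. The summit-to-flank ratio of TTAATT divided by that of the permuted core TATTAT was 0.878 (95% bootstrap interval 0.632 to 1.21), and both sequences were less frequent at summits. Against windows of matched GC content the cores were neither higher nor lower past the threshold, with 0.109 points for TTAATT. Those windows could hold coding sequence, which the summits rarely did, so they control for GC content alone. A modest preference for the core within part of the peaks stays open, since the interval of that ratio reaches above 1.

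The excess of regions around cog-1 may come from extra copies of the locus carried by the transgene. In the pooled list, 23 regions lay in the 30 kb from 20 kb upstream to 10 kb downstream of the cog-1 start, against 6 and 7 in the 30 kb on either side. The counts were 20 against 4 and 5 in replicate 1, and 27 against 4 and 3 in replicate 2. This stretch was chosen after the positions were seen, so its contrast restates the crowding and is not separate evidence. No protein-coding gene lay between the end of R05H10.3 (14883054) and the cog-1 start, whereas genes lay in both flanking stretches. The counts were not adjusted for that. The test set beforehand required a high median signal in both replicates, and the lower of the 2 percentiles was 44.4 while the other was 92.8, which meets neither outcome. Extra copies and binding of COG-1 across its own regulatory sequence cannot be told apart here, because only lists of regions were analysed and not read depth or a control library of the same strain.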
